A study of Mus musculus with 11 samples.

How the data were processed

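RNA was sequenced from hindlimb muscle of mice that carry a tamoxifen-inducible Cre recombinase at the Hic1 locus, a tdTomato reporter and either 2 wild-type Ctnnb1 alleles (WT) or 1 allele with loxP sites around exon 3 (WT/flox). Recombination of that allele removes exon 3, the part of beta-catenin that holds the phosphorylation sites for its degradation, and leaves a stable protein. Per the labels' protocols, mesenchymal progenitors were sorted as CD45-negative, CD31-negative, Sca1-positive, tdTomato-positive and alpha7-negative cells, and whole lysate was made from the tibialis anterior muscle. Libraries were made with a stranded poly(A) mRNA kit and read as paired ends of 43 bp on an Illumina sequencer, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20, Bowtie, STAR and the genome build mm10; the counting program and its strand setting are not given in the sources used here.

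The deposited values are counts per gene symbol, in 1 table for the sorted cells and 1 for the lysates. Both tables were found to hold whole numbers for the 24421 symbols, with 0 rows that name no gene, and the mitochondrial share of counts was 0 because no mitochondrially encoded gene is among the symbols. Of these symbols, 23376 matched gene names of GENCODE mouse release M21, from which coordinates on GRCm38 (mm10) were taken. Where strand use in counting is not known, reads of a gene and of an overlapping antisense gene cannot be told apart. The named genes with a listed antisense neighbour are Actc1, Adamts9, Bmp6, Col4a1, Ctnnb1, Fam78a, Mybph, Rab15, Tmem132c and Tmem51, with Abcc9, Aldoa, Cdh5, Cnp, Des, Eng, Itga7 and Xist among the markers. Hmga2-ps1 is a pseudogene that can share reads with Hmga2, and its values are uncertain for that reason.

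Total counts ran from 13119843 to 16805238 per progenitor library and from 16892158 to 19449227 per lysate library. The deposited sample table of the lysates gives the cell type as FAPs, as does that of the sorted cells, in conflict with the labels, which call these libraries whole muscle lysate. The labels were followed, and the gene with the highest count in each lysate library was Myh4 or Atp2a1, both of muscle fibres. Groups were taken from the labels, which name 11 distinct animals: 3 WT and 3 WT/flox for the progenitors, 2 WT and 3 WT/flox for the lysates. P-values therefore measure the spread between animals. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 9.55 to 84.1), and pairs within a group correlated at 0.959 to 0.991 across genes. The authors' sample tables give a sex, which matched Xist and Ddx3y counts in 11 of 11 libraries: 1 female and 2 males in each progenitor group, and males in the lysates. One WT/flox progenitor library, 74A3, is labelled day 56 after tamoxifen while the other 5 are labelled day 14. The lysates are labelled day 56.

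Each material was tested alone with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, robust dispersion estimates, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are TMM-scaled CPM, as mean ± SD. Fold changes are log2 of WT/flox over WT with the SE implied by the F statistic. In simulated counts with 200 changed genes, the progenitor test recovered 67% of 2-fold and 97% of 4-fold changes with 8 false calls, and the lysate test 75% and 97% with 12 false calls. The changed genes were drawn only from genes above a floor of expected count, and genes were simulated independently. Recovery for genes with few counts was therefore not measured. Unchanged simulated data gave 0 calls in the progenitor design and 1 in the lysate design.

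The gene lists, tests, alternatives and the rule for named genes were set before the data were examined. For each material the rule names Ctnnb1 and Hic1; the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean log2 CPM of at least 1, libraries that do not overlap between genotypes, and a symbol that is not a predicted model; up to 4 called members per list by adjusted p; and the 2 most abundant members of each list of other cell types, sex or dissociation. Of 33 gene lists, those with at least 5 tested members (22 for the progenitors, 30 for the lysates) were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were counted after adjustment over all genes tested and adjusted over the list alone. Medians and means given for lists or sets with a camera test are of the voom values, and can differ from those of edgeR fold changes. Medians in the part on results flagged for a closer look are of edgeR fold changes. Genes that changed in progenitors were tested as 2 sets in the lysates with camera, and a joint edgeR fit over the 11 libraries tested the interaction of genotype and material. Material and day change together in that fit.

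Alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in every library of a genotype, robust estimation off, a fit over all libraries, sex or identifier prefix as a covariate, sex-linked genes left out, and each library left out in turn. The replicate number of the authors' sample tables was added as a block after the data were seen. Where a group summed to 0 counts, a fold is a lower bound against 3 counts over that group. Where it summed to 1 to 3 counts, a ratio is given with an exact 95% interval. Such intervals cover counting error only.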

Results

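Transcript levels were compared between WT and WT/flox mice in sorted muscle mesenchymal progenitors, also called fibro/adipogenic progenitors, and in whole tibialis anterior muscle. The progenitor data comprised 3 WT and 3 WT/flox libraries of 13119843 to 16805238 counts, and the muscle data 2 WT and 3 WT/flox libraries of 16892158 to 19449227 counts. The series title links activation of beta-catenin in these progenitors to loss of muscle mass. The comparisons therefore ask which transcripts differ in the recombined cells and which differ in the muscle that contains them.

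The floxed gene was measured first. Ctnnb1 (ENSMUSG00000006932, GRCm38 chromosome 9, 120929216 to 120960507) reached 482 ± 38.3 CPM in WT and 402 ± 23.1 CPM in WT/flox progenitors (SD, n = 3 each), a log2 fold change of -0.26 (SE 0.17) that did not pass the edgeR test (adjusted p = 0.673). In muscle it was 297 ± 37.6 CPM in 2 WT and 297 ± 11.7 CPM in 3 WT/flox libraries (adjusted p = 0.997). The deleted exon 3 spans 120950522 to 120950749, 228 bp of the 15-exon transcript ENSMUST00000007130, so a count over the whole gene does not check its removal. Hic1, the driver locus, was at 100.4 ± 11.4 and 84.0 ± 13.3 CPM in WT and WT/flox progenitors (adjusted p = 0.711), and at 5.19 ± 0.275 and 6.18 ± 0.661 CPM in muscle (adjusted p = 0.780).

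In WT/flox progenitors the transcriptional targets of canonical Wnt signalling rose together. Axin2, a negative-feedback scaffold of the pathway (chromosome 11, 108920349 to 108950783), went from 3.47 ± 0.696 to 154 ± 17.2 CPM (log2 fold change 5.47, SE 0.22, adjusted p = 4.4e-06, n = 3 against 3). Notum, a secreted carboxylesterase that inactivates Wnt ligands (chromosome 11, 120653788 to 120661175), went from 0.263 ± 0.333 to 186 ± 41.1 CPM (9.32, SE 0.49). Nkd1 rose by 4.49 (SE 0.20) and Nkd2 by 3.53 (SE 0.17) on the log2 scale, and the transcription factor Tcf7 by 6.05 (SE 0.36). Of 15 tested members of the Wnt target list 10 were higher and 0 lower, 13 being higher when adjusted over the list alone; 10 were also higher without library 74A3. The list's median log2 fold change was 2.66 (camera adjusted p = 3.6e-26; adjusted p = 0.00687 with an estimated correlation). Among the 5 members that did not pass were Myc (0.26, SE 0.23, adjusted p = 0.864) and Wif1 (-0.81, SE 0.44, adjusted p = 0.568), both singled out after their values were seen. Lef1 had 4 counts over the WT and 6 over the WT/flox libraries and was not tested. The other untested members were Dkk1 (0 counts over WT and 79 over WT/flox), Sp5 (1 and 20), Lgr6 (0 and 4) and Rnf43 (1 and 0).

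**Figure D1:**
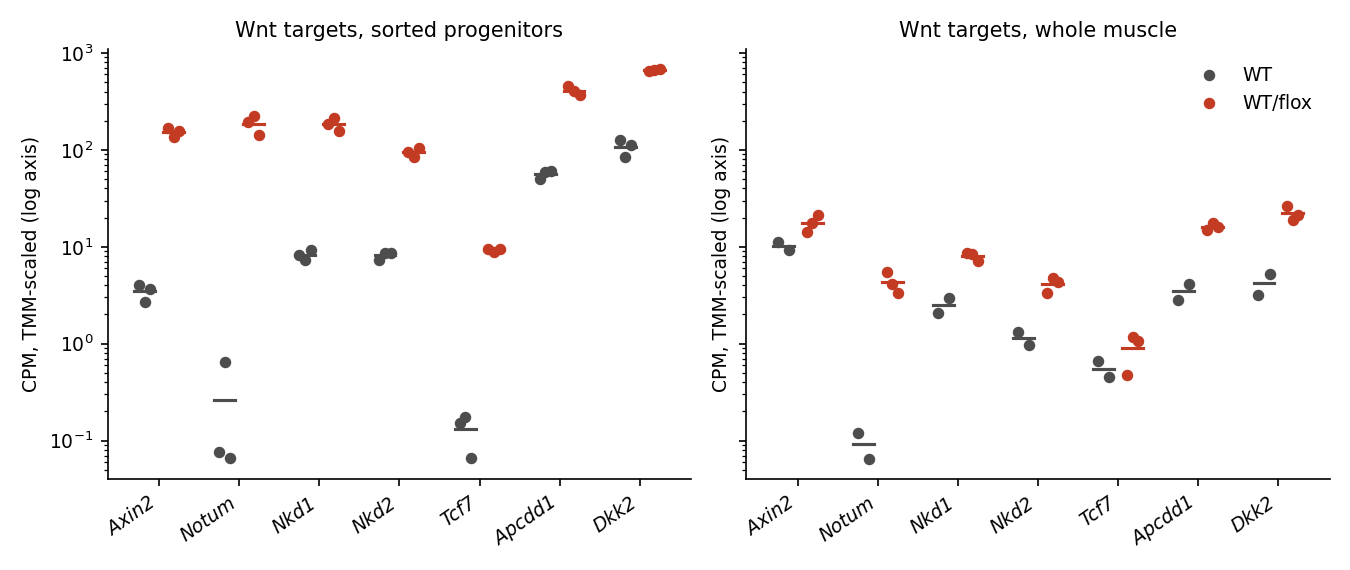
CPM (TMM-scaled, log axis) of 7 Wnt targets in each library of sorted progenitors (left) and whole muscle (right). Points are libraries, grey WT and red WT/flox, and bars are means; Axin2 averages 3.47 CPM in WT and 154 CPM in WT/flox progenitors, while Tcf7 overlaps between genotypes in muscle.

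Across all 12392 genes tested in progenitors, edgeR called 454, 290 higher and 164 lower in WT/flox, of which 370 changed at least 2-fold. Genotypes lay apart on the first principal component, which held 44.8% of the variance. Libraries did not overlap between genotypes for 16.9% of genes, where chance gives 10%. With the 5 libraries labelled day 14 (without 74A3) 262 genes were called, 255 of them among the 454, and the 454 genes all kept their sign. Without 72B7, 266 were called; DESeq2 called 755.

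Large rises outside the Wnt target list included Rerg, a Ras-related growth inhibitor (log2 fold change 6.10, SE 0.41), the adenylyl cyclase Adcy1 (5.94, SE 0.67), Wt1, a mesothelial and kidney transcription factor (5.63, SE 0.76), the cytochrome P450 Cyp2f2 (5.42, SE 0.38) and Igfbp2 (5.37, SE 0.62), all past the edgeR threshold with n = 3 against 3. Ces1f, a carboxylesterase, had 0 counts in WT and 268 in WT/flox libraries, at least 100.4-fold higher against 3 counts over the WT group. Gdnf, a neurotrophic ligand, had 3 counts over the WT libraries, and its ratio of WT/flox to WT was 56.6 (exact 95% counting interval 18.99 to 277). Its signalling receptor Ret fell from 264 ± 98.4 to 35.3 ± 8.67 CPM (-2.91, SE 0.31, adjusted p = 7.1e-04). Other falls were those of the metalloprotease Tll2 (-5.24, SE 0.60), Syt13 (-4.92, SE 0.95), the adaptor Blnk (-3.33, SE 0.46), Mrgprg (-3.29, SE 0.70), Fam78a (-3.15, SE 0.48), Susd5 (-2.94, SE 0.52), Tmem51 (-2.71, SE 0.44), the collagen gene Col6a6 (-2.58, SE 0.40) and the chemokine Cxcl13 (-2.50, SE 0.50). Without library 74A3 the log2 fold changes of Syt13 (-4.53), Mrgprg (-3.33), Susd5 (-2.66) and Cxcl13 (-2.37) no longer passed.

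Among 31 tested Wnt ligands, receptors and secreted modulators, 9 were higher and 0 lower, while the list as a whole did not pass (camera adjusted p = 0.123). Sfrp1 went from 97.5 ± 3.75 to 273 ± 28.8 CPM (1.49, SE 0.16) and Sfrp2 from 93.9 ± 32.0 to 406 ± 35.7 CPM (2.11, SE 0.26); both encode secreted Frizzled-related proteins. The receptors Fzd1 (1.37, SE 0.18) and Fzd10 (2.93, SE 0.38) also rose. Adjusted over the list alone, 10 were higher and 7 lower. Without library 74A3 8 were higher over all genes.

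Secreted factors with known effects on muscle changed in both directions: 3 of 28 tested were higher and 4 lower, and the list did not pass as a whole (camera adjusted p = 0.455). Inhba, which encodes the activin A subunit, went from 12.1 ± 4.74 to 132 ± 26.7 CPM (3.45, SE 0.28, edgeR adjusted p = 1.3e-04). Igf1, a growth factor for muscle, went from 277 ± 24.7 to 887 ± 250 CPM (1.68, SE 0.23), and Igfbp3, an IGF-binding protein, from 150 ± 25.5 to 612 ± 162 CPM (2.03, SE 0.24). Bmp6 fell from 37.7 ± 10.1 to 12.8 ± 0.461 CPM (-1.56, SE 0.21). Fst, which encodes the activin-binding protein follistatin, fell from 245 ± 27.7 to 103 ± 27.7 CPM (-1.24, SE 0.22). Igf2 and Gdf10 were the other members that fell; Fst, Igf2 and Gdf10 were singled out after their values were seen. Adjusted over the list alone, 7 were higher and 4 lower, and without library 74A3 3 were higher and 3 lower over all genes.

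**Figure D2:**
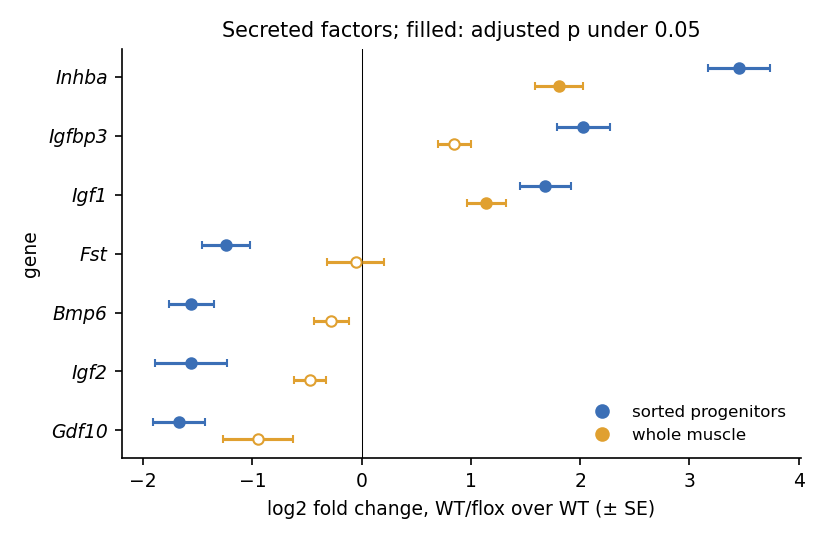
Log2 fold change of WT/flox over WT (± SE) for 7 secreted factors called in progenitors, in sorted progenitors (blue, n = 3 against 3) and whole muscle (orange, n = 2 against 3). Filled points have an edgeR adjusted p under 0.05; Inhba is at 3.45 in progenitors and 1.81 in muscle, and Fst at -1.24 in progenitors.

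Matrix genes were likewise mixed. Of 30 tested collagens, matrix proteins and cross-linkers 7 were higher and 1 lower (camera adjusted p = 0.149; 9 higher and 5 lower adjusted over the list alone). Fbn2, a microfibril protein, rose by 3.89 (SE 0.37), Col12a1 by 2.14 (SE 0.22), Col8a1 by 1.74 (SE 0.23), and Thbs2 from 504 ± 28.9 to 1759 ± 198 CPM (1.80, SE 0.19). Among 17 matrix proteases and inhibitors, Adamts9 (1.52, SE 0.33) and Ctsk (0.87, SE 0.19) were higher and Adamts15 was lower (-1.48, SE 0.21); the list did not pass (camera adjusted p = 0.455; 3 higher and 2 lower adjusted over the list alone). In the chemokine, cytokine and complement list 1 of 22 was higher, complement factor Cfb (1.55, SE 0.28), and 6 were lower, among them Ccl2 (-1.61, SE 0.27) and Ccl11 (-0.98, SE 0.19), with a camera adjusted p of 0.532. Adjusted over the list alone, 5 of them were higher and 7 lower. Without library 74A3 the matrix list had 6 higher and 0 lower, and the protease and chemokine lists each had 0 higher and 1 lower in edgeR, Adamts9 (1.60), Ctsk (0.76), Cfb (1.51) and Ccl11 (-1.04) keeping similar log2 fold changes but no longer passing with fewer libraries.

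Progenitor identity genes were mostly level: 20 of 22 were not called, Tcf7l2, a Wnt effector, was higher (2.10, SE 0.17) and the homeobox gene Meox1 lower (-1.62, SE 0.19); the list did not pass (camera adjusted p = 0.752). The osteochondrogenic list was lower (camera adjusted p = 0.0485; adjusted p = 0.802 with an estimated correlation), with 1 of 10 members called, Sox9 (-1.17, SE 0.25). In the tendon list Mkx (1.28, SE 0.27) and Thbs4 (0.90, SE 0.19) were higher and Cilp2 (-1.36, SE 0.31) was lower (camera adjusted p = 0.123). In the TGF-beta and BMP list Nog was higher (1.34, SE 0.31) and Bmper, which went from 206 ± 6.03 to 103 ± 16.1 CPM, lower, with a camera adjusted p of 0.755. Adjusted over the list alone, identity genes gave 2 higher and 1 lower, osteochondrogenic 0 and 3, tendon 2 and 3, and TGF-beta and BMP 2 and 2. Without library 74A3 edgeR called 0 members of the osteochondrogenic, tendon and TGF-beta lists, Sox9 (-1.05), Mkx (1.22), Thbs4 (0.82), Cilp2 (-1.25), Nog (1.41) and Bmper (-0.94) keeping similar log2 fold changes but no longer passing with fewer libraries. In the voom values, median and mean differed in sign for the identity (-0.06 and 0.04), TGF-beta and BMP (0.04 and -0.02), chemokine (0.03 and -0.14) and endothelial (-0.03 and 0.14) lists. The edgeR test called 0 members, over all genes or adjusted over the list alone, of the adipogenic (camera adjusted p = 0.555), myofibroblast (0.492, with 1 higher without 74A3), cell cycle (0.555), interferon (0.484), ribosomal protein (0.173) and oxidative phosphorylation (0.143) lists. The ribosomal list was higher by camera without 73C3 (adjusted p = 1.0e-12), 74A1 (0.00986) or 74A3 (0.00722). Oxidative phosphorylation was lower without 72B7 (camera adjusted p = 2.6e-06), 74A2 (8.1e-04) or 72B8 (0.0155).

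Marker lists of other cells took small shares of counts in the sorts, though not all took less than in whole muscle. The mural list took 0.0701 to 0.0908% in WT sorts and 0.0407 to 0.0655% in WT muscle. The glial list took 0.0513 to 0.0656% in WT sorts and 0.0184 to 0.0218% in WT muscle. In WT muscle the endothelial list took 0.0658 to 0.0772%. The immune list took up to 0.00204% of counts in any progenitor library. The endothelial list took 0.0598 to 0.0731% in WT and 0.0473 to 0.0506% in WT/flox libraries. Abundant myofibre transcripts took 0.0425 to 0.0746% in WT and 0.0352 to 0.0461% in WT/flox libraries; that list was lower in WT/flox (median -1.17, camera adjusted p = 7.1e-04; adjusted p = 0.855 with an estimated correlation), with 0 of 16 members called over all genes and 10 lower adjusted over the list alone; without library 72B8, 9 were lower over all genes. Kdr, the VEGF receptor used as an endothelial marker, rose from 6.65 ± 3.57 to 125 ± 40.4 CPM (4.23, SE 0.44), while Tek, another endothelial receptor, fell from 377 ± 49.9 to 152 ± 19.05 CPM (-1.31, SE 0.18), and the mural marker Cspg4 fell by 2.24 (SE 0.30) on the log2 scale. The endothelial (camera adjusted p = 0.756), mural (0.484), glial (0.216) and muscle stem cell (0.123) lists did not pass. Without library 74A2 the endothelial (camera adjusted p = 7.5e-04), muscle stem cell (0.0165) and glial (0.0403) lists were lower in WT/flox. The muscle stem cell list was also lower without 72B7 (camera adjusted p = 0.0212). The immediate-early genes Fos and Jun did not pass (edgeR adjusted p = 0.895 and 0.996), and the dissociation list had 0 called members of 21 (camera adjusted p = 0.171). That list was lower in WT/flox without library 72B8 (camera adjusted p = 1.4e-06) and without 74A1 (0.0131). It took 0.843% of counts in WT library 72B8, against 1.93% in 74A2 and 1.73% in 73C3.

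In whole muscle at day 56 Mybph, Csrp3 and Ankrd2 were among the called genes with the largest falls in WT/flox, and Mss51 and Igfn1 among those with the largest rises. Mybph, a myosin-binding protein (chromosome 1, 134193448 to 134201232), went from 79.3 ± 63.8 CPM in 2 WT to 1.45 ± 0.452 CPM in 3 WT/flox libraries (log2 fold change -5.78, SE 0.57, adjusted p = 0.00863). Csrp3, a stretch-responsive Z-disc protein (chromosome 7, 48830398 to 48848033), went from 1028 ± 750 to 51.9 ± 13.3 CPM (-4.31, SE 0.46), and Ankrd2, a stress-responsive sarcomeric ankyrin protein, from 1021 ± 665 to 74.5 ± 16.2 CPM (-3.78, SE 0.40). The cardiac actin gene Actc1 fell from 107 ± 1.61 to 18.01 ± 5.05 CPM (-2.58, SE 0.22), the M-band gene Myom3 by 2.21 (SE 0.21), the small heat shock gene Hspb7 by 1.79 (SE 0.23) and Casq2, the slow and cardiac calsequestrin, by 1.10 (SE 0.14) on the log2 scale. Mss51 rose from 29.9 ± 6.66 to 401 ± 74.8 CPM (3.74, SE 0.24, edgeR adjusted p = 0.00546), and Igfn1, a sarcomere-associated protein gene, from 33.0 ± 17.97 to 313 ± 65.4 CPM (3.24, SE 0.37).

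**Figure D3:**
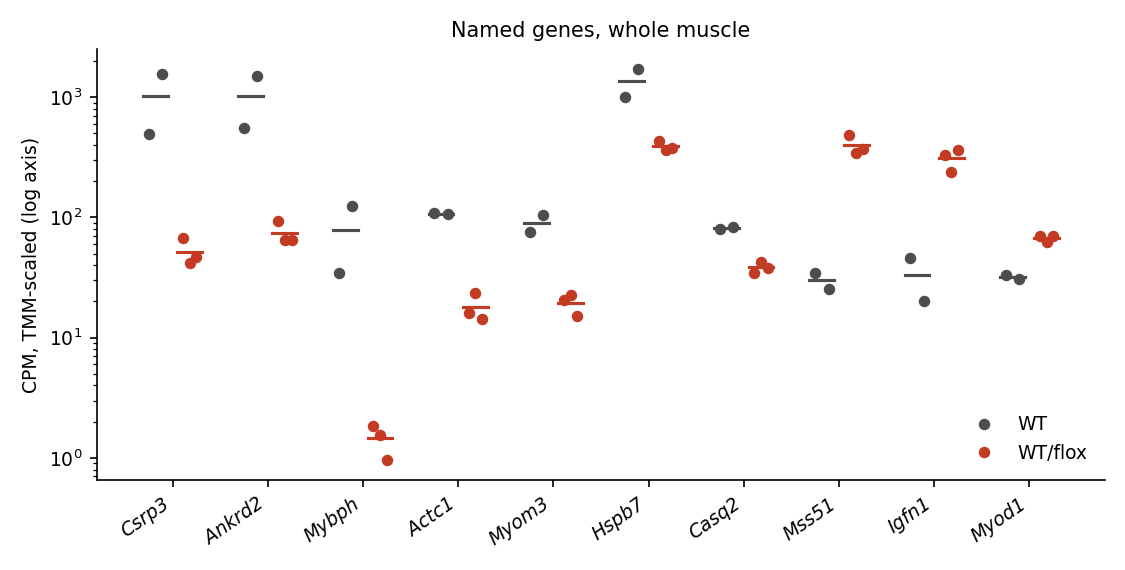
CPM (TMM-scaled, log axis) of 10 genes named in the text in each whole-muscle library, grey for 2 WT and red for 3 WT/flox, with bars at the means. Actc1 averages 107 CPM in WT and 18.01 CPM in WT/flox, and Mss51 29.9 and 401 CPM.

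Of 12654 genes tested in muscle, edgeR called 92, 65 higher and 27 lower, 87 of them at least 2-fold. The first principal component (46.9% of the variance) did not separate the genotypes, and 25.3% of genes did not overlap between them, where chance gives 20%. Without library 71B5 edgeR called 0 genes (smallest adjusted p 0.0532; 1023 at an unadjusted p under 0.05; DESeq2 162, limma voom 0), although 92 of the 92 kept their sign and an unadjusted p under 0.05, with a median log2 fold change in size of 1.56 against 1.55; without 71B4 it called 25, without WT library 73A5 239 (109 higher, 130 lower) and without 73A7 207. DESeq2 called 267 with all 5 libraries, 59.6% of them higher against 70.7% with edgeR. The WT identifiers all begin with 73A and the WT/flox identifiers with 71B, so that any difference between those series cannot be told apart from genotype.

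Wnt-related genes were higher in WT/flox muscle as well. Notum had 3 counts over the WT and 252 over the WT/flox libraries, a ratio of 46.3 (exact 95% counting interval 15.7 to 226). Dkk2, a secreted Wnt antagonist, went from 4.21 ± 1.47 to 22.1 ± 3.70 CPM (2.40, SE 0.26), Apcdd1 from 3.46 ± 0.910 to 16.2 ± 1.42 CPM (2.23, SE 0.22), and Nkd1 from 2.52 ± 0.603 to 8.03 ± 0.7501 CPM (1.67, SE 0.23). Of 14 tested Wnt targets 5 were higher and 0 lower, with 7 higher when adjusted over the list alone (camera adjusted p = 4.0e-08; adjusted p = 0.227 with an estimated correlation). Axin2, at 0.80 (SE 0.22), had an edgeR adjusted p of 0.22. In the ligand and receptor list, Fzd1 (1.12, SE 0.17) and Sfrp1 (1.54, SE 0.21) were higher, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0231, and 0.581 with an estimated correlation). Without WT/flox library 71B5 the ligand and receptor list did not pass (camera adjusted p = 0.0806).

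Other rises in muscle were those of the enkephalin precursor Penk (3.21, SE 0.30), Ildr1 (4.53, SE 0.34), Tmem132c (4.58, SE 0.36), Wisp2 (2.79, SE 0.30), Prima1, a membrane anchor of acetylcholinesterase (2.61, SE 0.24), and Dkk3 (2.39, SE 0.25). Falls included the imprinted long non-coding RNA Rian (-2.11, SE 0.17), Vash2 (-2.07, SE 0.32), Rab15 (-1.82, SE 0.24) and the pseudogene Hmga2-ps1 (-2.41, SE 0.35). Among 24 secreted factors Inhba (1.81, SE 0.22) and Igf1 (1.14, SE 0.18) were higher and 0 lower, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0221, and 0.581 with an estimated correlation). The secreted-factor list did not pass without WT/flox library 71B5 (camera adjusted p = 0.0806). Lox, a collagen cross-linker (1.51, SE 0.16), and Thbs2 (1.11, SE 0.15) rose while Col5a3 (-1.21, SE 0.19) and Col4a1 (-0.79, SE 0.13) fell among 29 matrix genes (camera adjusted p = 0.423; 4 higher and 5 lower adjusted over the list alone). Also higher were the BMP antagonist Nog (1.41, SE 0.23) and the inhibitory Smad7 (1.13, SE 0.18), the progenitor marker Cxcl14 (1.54, SE 0.26) and the myogenic factor Myod1 (1.09, SE 0.14). Their lists were the TGF-beta and BMP list (camera adjusted p = 0.0820), the progenitor identity list (0.00168; adjusted p = 0.707 with an estimated correlation) and the muscle stem cell list (0.723). Adjusted over the list alone they gave, in that order, 5, 4 and 1 higher and 2, 0 and 1 lower. The identity list took 0.135% of counts in WT library 73A5 and 0.212% in WT library 73A7. In WT/flox libraries it took 0.210 to 0.265%, so its rise rests largely on 73A5. The chemokine, cytokine and complement list was higher by camera (adjusted p = 0.00439, and 0.666 with an estimated correlation). It took 0.0205% of counts in WT library 73A5, 0.0256% in 73A7 and 0.0259 to 0.0346% in WT/flox libraries. The immune list took 0.00515% in 73A5, 0.0156% in 73A7 and 0.0113 to 0.0145% in WT/flox libraries. Both lists were lowest in 73A5.

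Genes of muscle atrophy did not move as a group. Of 23 tested atrogenes 1 was called, the transcription factor Foxo1 (1.03, SE 0.14, edgeR adjusted p = 0.0213), and the list did not pass (camera adjusted p = 0.723; 1 higher and 2 lower adjusted over the list alone); the ubiquitin ligases Fbxo32 (0.22, adjusted p = 0.81) and Trim63 (-0.09, adjusted p = 0.91), singled out after their values were seen, did not pass. Proteasome subunits had a median log2 fold change of -0.17 with 0 of 37 called (camera adjusted p = 2.7e-04; adjusted p = 0.707 with an estimated correlation). Fast-fibre genes had a median of -0.39 with 0 of 13 called (camera adjusted p = 0.00528; adjusted p = 0.707 with an estimated correlation) and took 16.2 to 17.5% of counts in WT and 12.9 to 16.02% in WT/flox libraries. Slow-fibre genes had a median of -0.27 and 1 of 10 called, Casq2 (camera adjusted p = 0.0417; adjusted p = 0.707 with an estimated correlation). In the regeneration list Csrp3 and Actc1 were lower and Myod1 higher; its camera test was lower (adjusted p = 0.0121; adjusted p = 0.707 with an estimated correlation) and its mean was -0.68 although its median was 0.02, with 1 higher and 6 lower adjusted over the list alone. Without WT library 73A7 the proteasome (median -0.05), fast-fibre (-0.16), slow-fibre (0.14) and regeneration (0.11) lists did not pass. Nor did these lists pass without WT/flox library 71B5 (camera adjusted p = 0.0723, 0.115, 0.517 and 0.0862, in that order). The neuromuscular junction and denervation list (camera adjusted p = 0.922) and the autophagy list (0.972) did not pass, with 0 members called by edgeR over all genes; adjusted over the list alone, 2 junction genes were lower. Median and mean differed in sign for atrogenes (0.16 and -0.01).

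The other lists had 0 members called over all genes by edgeR in muscle. Oxidative phosphorylation (median -0.18, camera adjusted p = 1.2e-04), glycolysis (0.0158), endothelial (median -0.28, 1.8e-04), mural (0.0443), glial (0.0231) and myofibroblast (0.00808) lists were lower by camera. With an estimated correlation their adjusted p values were 0.766, 0.707, 0.287, 0.581, 0.707 and 0.707. Without 73A7 the oxidative phosphorylation (median -0.0021), glycolysis (-0.11), glial (-0.13) and myofibroblast (-0.08) lists did not pass, nor the mural list (-0.11) without 73A5. Without WT/flox library 71B5 the oxidative phosphorylation (camera adjusted p = 0.427), glycolysis (0.484), glial (0.101), myofibroblast (0.0600) and mural (0.0723) lists did not pass. The mural list also did not pass without 71B3 (0.0790) or 71B4 (0.0786). Immune (0.0728), matrix protease (0.477), adipogenic (0.247), osteochondrogenic (0.476), tendon (0.922), cell cycle (0.222), interferon (0.386), dissociation (0.247) and ribosomal protein (0.146) lists did not pass the camera test, adjusted p in parentheses. Adjusted over the list alone, 1 protease, 1 tendon and 1 dissociation gene were higher, and 1 gene each of the mural, glycolysis and dissociation lists was lower. The tendon list's median (-0.02) and mean (0.02) differed in sign. In all, 15 of 30 lists passed camera with the preset correlation and 0 with an estimated one.

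Genes changed in progenitors shifted the same way in muscle. Of 253 genes higher in WT/flox progenitors and tested in muscle, 203 (80.2%) had a positive log2 fold change there, against 51.1% of all 11506 genes tested in both, and the set was higher (camera p = 2.4e-22; p = 0.00656 with an estimated correlation). Of the 133 genes lower in progenitors and tested in muscle, 32 (24.1%) had a positive log2 fold change there. As a set they were lower (camera p = 2.5e-07, and p = 0.0402 with an estimated correlation). There were 28 genes called higher in both, where independent lists would share 1.19 (exact hypergeometric p = 9.5e-33), including Notum, Nkd1, Nkd2, Dkk2, Apcdd1, Fzd1, Sfrp1, Inhba, Igf1, Lox, Thbs2, Penk, Wisp2 and Nog. Hmga2-ps1, Plau and Rab15 were lower in both, and Fam78a was lower in progenitors and higher in muscle; Plau was singled out after its values were seen. The animals of the 2 materials are different, so no control library is shared.

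**Figure D4:**
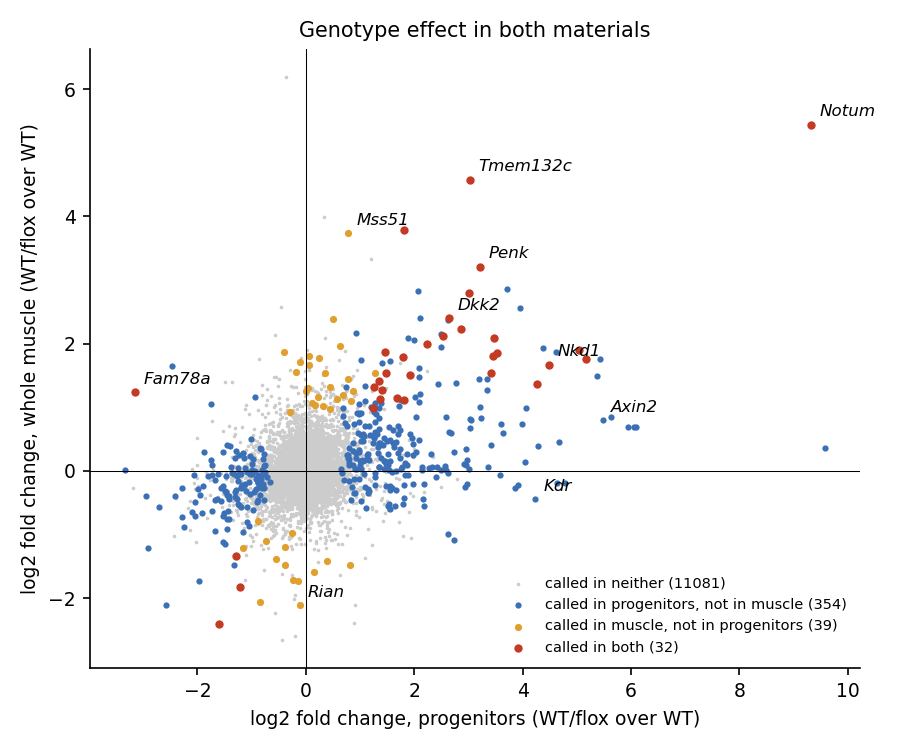
Log2 fold change of WT/flox over WT in progenitors (x) and whole muscle (y) for the 11506 genes tested in both, coloured by where edgeR called them. Of these, 32 were called in both, 354 in progenitors and not in muscle, and 39 in muscle and not in progenitors; Notum lies at 9.32 and 5.44.

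The interaction of genotype and material passed for 106 of 13781 genes, 34 with a more positive change in muscle and 72 with a more positive change in progenitors. The log2 fold change in muscle minus that in progenitors was -4.63 (SE 0.29) for Axin2, -2.77 (SE 0.28) for Nkd1 and 3.004 (SE 0.38) for Mss51. Material and day after tamoxifen change together here, and the count was 54 without WT muscle library 73A7, 61 without 71B4, 66 without 71B3 and 70 without progenitor library 74A1.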

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

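Apart from the interaction, the mixing test in the next paragraph and the comparisons of day and identifier series, the tests in this part were chosen after the results were seen. The interaction of genotype and material, tested in the joint edgeR fit, passed for 21 of the named genes, and each is given as the log2 fold change in muscle minus that in progenitors. More positive in progenitors were Axin2 (-4.63), Nkd1 (-2.77), Rerg (-5.35), Kdr (-4.62), Tcf7 (-5.30), Adcy1 (-5.20), Col12a1 (-2.07), Fzd10 (-3.13), Ces1f (-9.08, a fitted value that depends on the prior count because WT progenitors had 0 counts), Cyp2f2 (-3.60), Tcf7l2 (-1.56), Gdnf (-4.72, from 3 WT progenitor counts), Nkd2 (-1.61), Adamts9 (-2.03) and Rian (-1.97, which fell in muscle). More positive in muscle were Fam78a (4.43), Mss51 (3.004), Prima1 (4.03), Blnk (3.39), Meox1 (1.64) and Bmp6 (1.33).

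Genes higher in WT/flox progenitors were also higher in muscle, by less. The median ratio of WT muscle to WT progenitor CPM over 22 identity genes was 3.20%. If progenitor RNA makes up that share of muscle RNA, mixing alone predicts the muscle change of each of the 253 genes. Observed minus predicted log2 fold change had a median of -0.076 (95% bootstrap interval -0.17 to -0.04), which excludes 0 but lies within the tolerance of 0.25 set beforehand. Dilution among other muscle RNA may thus account for the smaller rise of the set in its median. Single genes varied, with quartiles of 0.516 and 4.62% for the muscle rise as a share of the progenitor rise. The interval holds the 3.20% share fixed. More progenitors in WT/flox muscle stay open as a contribution: the set's median exceeded that of 20 identity genes not called in progenitors by 0.18 (interval -0.04 to 0.41). Day and material cannot be told apart, since 0 materials were measured at both days in both genotypes, and a change in the cells between days 14 and 56 was not tested.

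The 27 genes lower in WT/flox muscle had a median log2 fold change of -1.48. A smaller share of slow fibres stays open. The 9 slow-fibre genes outside the pattern had a median of -0.32 (SD 0.24), a smaller fall. That gap cannot decide the question, because the called member Casq2 was left out of the 9 while the 27 were selected by their call. The median of the slow-fibre list also had opposite signs when one or the other WT library was left out. Regenerating fibres in the WT muscles stay open: 12 developmental and regeneration genes outside the pattern had a median of 0.048 but a wide spread (SD 0.79), which was chosen as the measure of spread after a median absolute deviation of 0.16 had been seen to exclude the explanation. Identifier series and genotype cannot be told apart, with 0 series holding both genotypes. A difference in the load on the muscle was not tested.

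Kdr rose in WT/flox progenitors, and endothelial cells in the WT/flox sorts are a candidate explanation. The other 16 tested endothelial markers had a median log2 fold change of -0.30 (SD 0.47) against 4.23 for Kdr, with Pecam1 at 6.83 ± 3.99 CPM in WT and 5.82 CPM in WT/flox, and all 17 list members passed the count filter in the progenitor data. The sort was CD31-negative, and these values argue against that source. A change of Kdr within the progenitors is one hypothesis left, not tested here.

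Other groupings of the 6 progenitor libraries were tested as well. The genotype split called 454 genes and the highest of the other splits 0; 1 of the 10 splits, the genotype split itself, gave as many. For gene lists past the camera threshold the genotype split gave 3 and the highest other 9, and 8 of the 10 splits, that one included, gave as many. The highest count of lists came from a split that mixes genotypes, so the number of lists past the threshold does not single out genotype. These splits used camera with the preset correlation of 0.01. Estimated correlations in the progenitors reached 0.87 for ribosomal protein and 0.76 for oxidative phosphorylation genes. Whether structure among the samples other than genotype adds to these counts was not tested. With 10 splits a share under 0.05 cannot be reached.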

How the results depend on the processing

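The replicate block, the Wnt-free sets, fry on the progenitor sets, the scaling without myofibre, stress and ribosomal genes and the extra tools without 71B5 were chosen after seeing the data. Over all alternatives, the 51 called named genes of the progenitors gave 918 values, of which 847 stayed past the threshold in the same direction, 71 no longer passed and 0 reversed. The 37 of muscle gave 518 values, of which 426 stayed, 92 no longer passed and 0 reversed. Gene lists were less stable. The 3 lists past the camera threshold in progenitors gave 30 values, of which 22 stayed and 8 were weaker. The 15 of muscle gave 120 values, of which 66 stayed, 53 were weaker and 1 reversed, and 0 of the 15 stayed the same throughout. Of 120 values of the 15 muscle lists not past it, 107 stayed, 9 were stronger and 4 reversed. Ctnnb1 passed under none of the settings tried, with adjusted p from 0.461 in progenitors and from 0.715 in muscle. Both progenitor-derived sets passed in muscle under every setting tried, with median log2 fold changes of 0.40 to 0.51 and -0.31 to -0.18. Counts that moved by over 1.5 times are the following, and the cause was not tested. Leaving out a library lowered the count in some settings and raised it in others. Progenitor genes numbered 755 with DESeq2 and 262 to 483 with one library left out. Progenitor lists numbered 1 with an estimated correlation, 1 with fry, and 2 to 8 with one library left out. Muscle genes numbered 267 with DESeq2, 139 with no filter and 0 to 239 with one library left out. Muscle lists numbered 0 with an estimated correlation, 2 with fry and 5 to 17 with one library left out. The interaction called 54 to 114 genes with one library left out. List medians in muscle with opposite signs without 73A5 and without 73A7, given in that order, were -0.29 and 0.57 for matrix genes, -0.47 and 0.45 for adipogenic, -0.42 and 1.28 for immune, -0.19 and 0.35 for ribosomal protein -0.73 and 0.14 for slow-fibre, -0.06 and 0.25 for matrix protease, -0.33 and 0.11 for tendon, -0.08 and 0.06 for muscle stem cell, -0.05 and 0.04 for autophagy, -0.29 and 0.11 for regeneration and 0.15 and -0.04 for Wnt ligand and receptor genes. The camera direction also differed between these settings for the osteochondrogenic, dissociation and atrogene lists; the single WT library left is assumed to vary like the others. With the replicate number as a block, 491 progenitor genes, 7 progenitor lists and 178 muscle genes were called. Deviations of same-numbered progenitor libraries correlated at 0.03, 0.29 and -0.13 and those of muscle at -0.02 and -0.48, so the numbers are not shown to pair the samples, although 72B8 with 72B7 and 74A2 with 74A1 also share identifier prefix and sex. Not every sample correlated best with its own number. With the identifier prefix as a block 566 progenitor genes were called, 382 of the 454 among them.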

Other observations

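The genes in this part were chosen after their values were seen. They form no list fixed beforehand, and no enrichment was tested. In WT/flox progenitors Ptn, a heparin-binding growth factor, went from 2.78 ± 0.986 to 99.0 CPM (log2 fold change 5.16, SE 0.38), and the receptor Ntrk2 rose by 1.45 (SE 0.18) on the log2 scale, while Ntf3 (-1.41, SE 0.20) and the cytokine receptor Lifr (-1.90, SE 0.21) fell; all passed the edgeR test with n = 3 against 3. In muscle Ptn (1.76, SE 0.28) and Ntrk2 (1.87, SE 0.22) were higher, and Ntf3 and Lifr did not pass.

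In WT/flox muscle Pmepa1 rose from 25.8 ± 10.2 to 81.4 CPM (1.66, SE 0.25) and Ldlrad4 (1.55, SE 0.24) and the activin and BMP receptor Acvr1 (0.98, SE 0.14) were higher as well, while the TGF-beta and BMP list fixed beforehand did not pass (camera adjusted p = 0.0820; adjusted p = 0.581 with an estimated correlation). In progenitors Pmepa1 (0.07, SE 0.19) and Ldlrad4 (-0.18, SE 0.20) did not pass. Among other genes that fell in muscle, Fhl1 went from 4973 ± 529 to 1517 CPM (-1.71, SE 0.19), and Flnc (-1.48, SE 0.18), Lmcd1 (-1.42, SE 0.18), Smox (-1.73, SE 0.15) and Slc25a25 (-1.48, SE 0.19) were lower. Ankrd1 (-1.69, SE 0.51), Xirp1 (-1.27, SE 0.23) and Nrap (-0.27, SE 0.15) did not pass, and these muscle calls, like the others, are lost without library 71B5, where edgeR called 0 genes (1023 at an unadjusted p under 0.05; DESeq2 162, limma voom 0) while the 92 genes kept a median log2 fold change in size of 1.56 against 1.55.

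Where genes were called higher in both materials, the rise in muscle CPM was a median 3.05% of the rise in progenitor CPM (quartiles 1.99 and 3.97%, 28 genes). These 28 were selected by their call in muscle. Over all 253 genes called higher in progenitors and tested in muscle the median was 2.51% (quartiles 0.516 and 4.62%). It was 3.19% over the 10 Wnt targets called in progenitors, not all of which were called in muscle. Among the 28, the muscle rise was 415% of the progenitor rise for Nog and 186% for Adamts8, and 0.987% for Lepr.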
